A study of Mus musculus with 2 samples.

How the data were processed

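The series holds CTCF ChIP-seq of liver from newborn mice (postnatal day 0) of the strain B6NCrl. CTCF is a zinc finger protein that binds an asymmetric DNA motif and, together with the ring-shaped cohesin complex, holds chromatin loops and domain borders in place. Per the labels, both samples are biological replicates of 1 group, made from pulverized livers pooled over several dissections. They carry the same biosample and donor labels, so the spread between them may be technical, and intervals and replicate ranges here cover no variation between litters. The sex of the mice was not collected, per the labels. A control experiment is named in the labels and was not analysed here.

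The authors deposited 5 peak lists in narrowPeak format on the mouse build mm10, per the labels. Each replicate has its own list, made from its own alignments and 1 further file of a kind that is not named, per the text deposited with the samples. A pooled list was made from the alignments of both replicates. The conservative and the optimal list were made from these 3 lists by the irreproducible discovery rate (IDR). This method keeps peaks whose rank repeats between lists. How its use differed for the conservative and the optimal list is not given. Aligner, peak caller, thresholds and versions are not given in the sources used here. The signal of each peak is the value the authors deposited in the signal column. Its scale is not stated, so it was used to describe, rank and filter peaks within a list. The deposited −log10 q value stops at 5.03 in the optimal list and is shared by 88.4% of its peaks, so it was not used to rank them. The deposited score ran from 537 to 1000 in both IDR lists and was not used in a test. The summit is the start of the peak plus the offset the authors deposited. Peaks of the commonest width, 284 bp, have their summit in the middle, and these make up 53.3% of the optimal list, 91.1% of the pooled list and 92.8% and 92.9% of the replicate lists. The replicate and pooled lists each end at exactly 300000 peaks, so they hold many weak calls and their lengths carry no information on binding. No read counts were used here, so the depth of each library is unknown and no interval on a peak's signal is given. Binomial intervals on shares are exact (Clopper-Pearson, 95%) and cover counting error over peaks or genes only.

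Lists were compared by summits within 100 bp of each other. From each replicate the 57220 strongest peaks were kept, as many as the optimal list holds, and the same share was taken after moving 1 list by 10 kb. Spearman's rho of the replicates' signals was taken across peaks, which are not independent replicates, so no p-value is given. Coordinates were set against GRCm38, the assembly that mm10 names, and the GENCODE M21 annotation. A summit within 1 kb of any annotated transcript start, internal starts included, was called a promoter peak. Other summits were called exonic, intronic or intergenic, in that order of priority. The background was 100 random placements of the summits on their own chromosomes outside assembly gaps. The 14-base CTCF core CCASYAGRKGGCRS, in IUPAC letters, was sought on both strands within 50 bp of the summit with at most 2 mismatches, and in a window displaced by 1 kb as a control. Neighbouring peaks with 1 best core match and at most 200 kb apart were sorted into tandem pairs (same strand), convergent pairs (forward core on the left, reverse core on the right) and divergent pairs. The observed shares were set against 100 shuffles of the strands within each chromosome. Permutation p-values are two-sided, and 0.0198 is the smallest that 100 draws can give. For the annotation they were made two-sided after one-sided values had been seen, which moved none across the threshold.

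Gene groups were tested with Fisher's exact test, two-sided, as the share of members with a promoter peak against all other protein-coding genes, with Benjamini-Hochberg adjustment over 19 lists and a threshold of 0.05. Promoters with a GC share of at least 50% and an observed over expected CpG ratio of at least 0.6 within 500 bp of the start were called CpG-rich, and an exact Cochran-Mantel-Haenszel test stratified by this class was an alternative. Both tests treat genes as independent. Genes in clusters are not, so their p-values may be too small. Such genes include those of the Hox, protocadherin and olfactory receptor lists and many cytochrome P450 genes. The gene lists, the landmark genes, the tests and the alternatives were chosen before the data were examined. The alternatives were the conservative list, the stronger 28610 peaks, each replicate alone, other distances, mismatches and overlaps, another background and another promoter class, and, chosen after the data were seen, pairs 50 to 200 kb apart. Genes are named by a rule set at the same time. It takes 27 landmark genes with their promoter peak or else the nearest peak, the 3 members of each list with the strongest promoter peak, the 10 strongest peaks, and the 3 strongest pooled peaks outside the optimal list. Some genes that the rule takes are not reported here. The symbol Ahsp, in the erythroid list, was not matched in the annotation and was left out. A total of 23 optimal peaks on unplaced or unlocalized scaffolds were left out of the annotation, motif and gene analyses.

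The steps were tested on simulated data. Matching recovered 75.0% of 2000 simulated sites, the share planted. The motif scan found 100.0% of 3000 planted cores. The orientation step returned 64.3% convergent pairs among 10000 simulated pairs, and 25.1% after shuffling. With peaks planted independently from gene to gene, random lists of 50 real protein-coding genes passed an unadjusted threshold of 0.05 in 4.50% of 400 draws. This does not show the error rate for clustered genes or for real peaks. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, pysam 0.24.0, samtools 1.23.1 and matplotlib 3.10.9 were used.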

Results

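CTCF binding was measured by ChIP-seq in liver of newborn mice, an organ in which hepatocytes and blood-forming cells lie side by side at this age. The series has 1 group with 2 replicates and no treatment, so the questions were where CTCF was bound, how well the replicates matched, and which genes carried a peak. The optimal IDR list held 57220 peaks, of which 57197 lay on assembled chromosomes. Their deposited signal ran from 4.12 to 701.8 with a median of 71.2, and the median width was 284 bp. All positions are on mm10.

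The strongest peak of the list lay in a coding exon of Gdf15, which encodes a stress-induced hormone, at chromosome 8 from 70629661 to 70630200, with a signal of 701.8. It ranked 1 in both replicate lists. The next was in the 5' UTR of Acbd4, 169 bp from a transcript start, on chromosome 11 from 103102643 to 103103057 (signal 675.7), over a perfect core match, CCACCAGGGGGCGC, at 103102815 to 103102828. The other peaks among the 10 strongest lay in introns of Fam129b and Pink1, at the promoters of Polr3gl, Comtd1, Iqsec1 and Gins4, and in intergenic sequence 13.5 kb from a start of Rbm19 and 17.8 kb from one of Enah. Pink1 encodes a mitochondrial kinase and Polr3gl a subunit of RNA polymerase III. All 10 carried the core within 50 bp of the summit, and 4 of them, at Acbd4, Rbm19, Pink1 and Enah, carried it without a mismatch. Their ranks were at most 10 in replicate 1 and at most 19 in replicate 2.

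The replicates placed their peaks at the same sites. Of the 57220 strongest peaks of replicate 1, 87.4% (95% interval 87.2 to 87.7) had a summit within 100 bp of one in replicate 2, against 0.965% after a shift by 10 kb. Of the optimal peaks, 55542 (97.1%) were matched in both replicate lists, and across these peaks Spearman's rho of the signal was 0.962. Both values come from a list made with IDR from the lists of these same replicates and the pooled list. They therefore do not measure agreement independently of that choice. Summits of the strongest 11444 peaks lay a median of 5 bp apart in the replicates, and those of the weakest 11444 lay 22 bp apart. Among the weakest, 86.3% were matched in both lists, compared with 99.97% among the strongest. Within 5 groups of 11444 peaks, from strongest to weakest signal, rho was 0.910, 0.795, 0.555, 0.0652 and -0.0998. The groups were cut by the signal of the optimal list, whose peaks all lie in the pooled list made from both replicates. Such a cut narrows the range within a group and can by itself lower rho or make it negative. These values therefore do not show how far weak peaks rank alike. The plot of replicate signals shows the widening at the weak end.

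**Figure D1:**
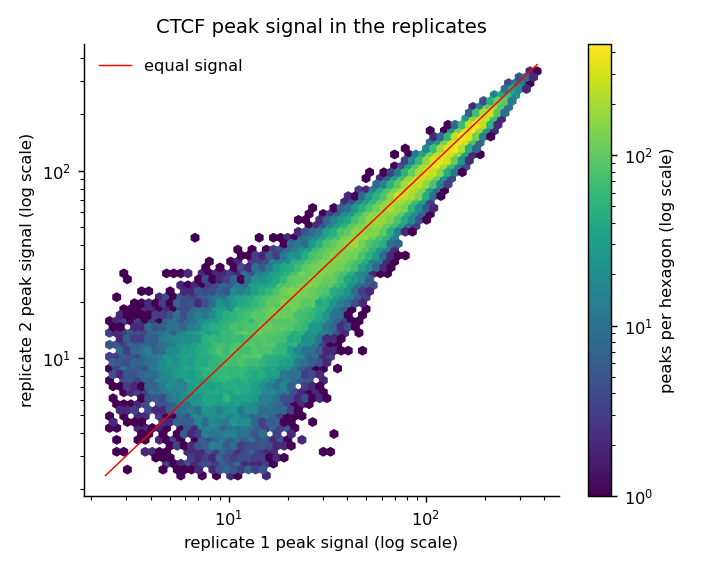
Signal of the 55542 optimal IDR peaks matched in both replicates, replicate 1 against replicate 2 on log axes, with color for the number of peaks per hexagon and a line at equal signal. The cloud is narrow at high signal and wide at low signal (rho 0.962 across peaks, not samples, in a list made with IDR from these replicates).

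Promoters held 11754 peaks, 20.55% of the list (95% interval 20.2 to 20.9; replicates alone 20.59% ± 0.12, SD, n = 2), while random placement put 6.39% there. The excess was 3.22-fold (two-sided permutation p = 0.0198, the smallest possible), and 1.87-fold over summits displaced by 10 kb. Exons outside promoters held 5.18%, 1.52 times the 3.41% of random placement (permutation p = 0.0198), but only 0.843 times the share of summits displaced by 10 kb. Introns held 40.5%, against 40.3% at random (permutation p = 0.198), and 0.860 times the share of displaced summits. Intergenic sequence held 33.8%, less than the 49.9% at random (permutation p = 0.0198), and 0.945 times the share of displaced summits. The median distance to a transcript start was 6.05 kb, 62.3% of summits lay within 10 kb of one, and 1.71% lay beyond 100 kb. Of 21938 protein-coding genes, 7943 (36.2%) had a promoter peak. The share was 53.8% (95% interval 52.8 to 54.8) of 9740 genes with a CpG-rich promoter and 22.1% (21.4 to 22.9) of the other 12198.

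The CTCF core motif was found at 40742 peaks, 71.2% (95% interval 70.9 to 71.6; replicates alone 70.9% ± 0.23, SD, n = 2), and in 2.98% of windows 1 kb away. Signal followed the match to the core. Peaks with a perfect core had a median signal of 228.1, those with 1 mismatch 118.2, those with 2 mismatches 62.2 and those with 5 mismatches 19.7. Among the 5720 strongest peaks 90.4% carried the core, and among the 5719 weakest 41.5%, as the plot of motif share by signal shows. The center of the core lay within 10 bp of the summit at 69.9% of the 39350 peaks with a unique best match. Peaks without the core were more often at promoters, 34.1% (95% interval 33.3 to 34.8) against 15.1% (14.7 to 15.4) of peaks with it, and their median signal was 35.7 against 98.8.

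**Figure D2:**
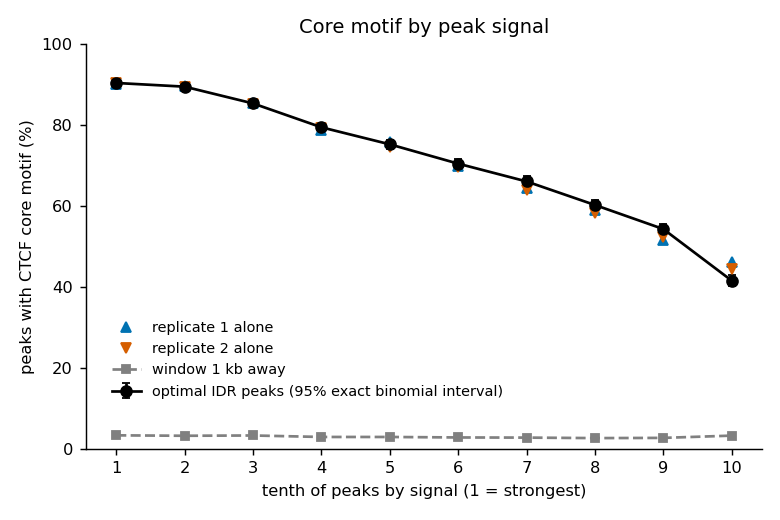
Percent of optimal IDR peaks with the CTCF core within 50 bp of the summit, in 10 equal groups from strongest to weakest signal, with exact 95% binomial intervals, each replicate alone, and windows 1 kb away. The share falls from 90.4% to 41.5%, while the displaced windows lie between 2.64% and 3.32%.

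Neighbouring CTCF cores pointed the same way more often than after shuffling. They pointed toward each other less often when close together and more often when far apart. Among all 26472 neighbouring pairs at most 200 kb apart, 52.9% were tandem (shuffled range 49.3% to 50.8%, permutation p = 0.0198) and 22.1% convergent (shuffled range 24.4% to 25.5%, permutation p = 0.0198, the smallest possible). The divergent share was 24.97%, within the shuffled range of 24.6% to 25.4% (permutation p = 0.970). The tandem excess was lost among the stronger 28610 peaks, where 50.2% of pairs were tandem (permutation p = 0.673) and 26.9% divergent. The direction of the convergent difference turned with distance, and among the 4623 pairs 50 to 200 kb apart, a range chosen after the data were seen, 28.2% were convergent (shuffled range 22.9% to 26.5%, permutation p = 0.0198). The convergent share was 19.3% (95% interval 18.3 to 20.3) for the 6414 pairs under 5 kb apart and 29.99% (27.7 to 32.3) for the 1564 pairs 100 to 200 kb apart.

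**Figure D3:**
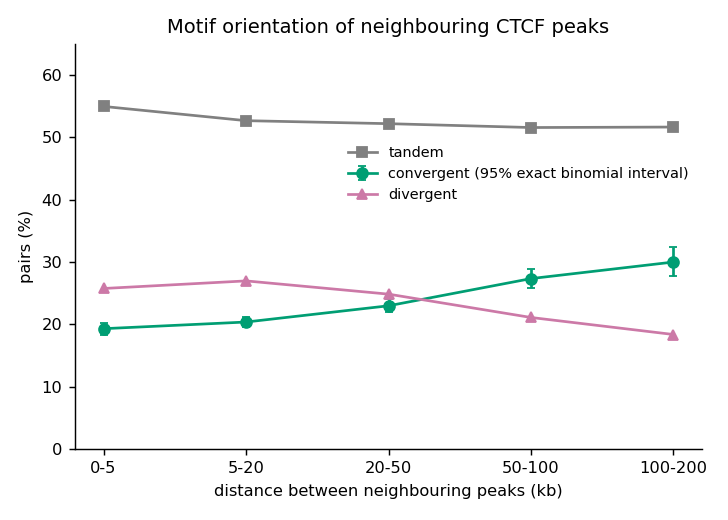
Percent of tandem, convergent and divergent pairs of neighbouring CTCF peaks by the distance between them in kb, with exact 95% binomial intervals for the convergent share. Convergent pairs go from 19.3% at 0 to 5 kb to 29.99% at 100 to 200 kb, and divergent pairs from 25.7% to 18.4%.

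Promoters of ribosomal protein genes carried a peak more often than those of other genes. Promoters of cytochrome P450 and olfactory receptor genes carried one less often. Peaks with and without the core were counted alike. Of 79 ribosomal protein genes, 50 (63.3%) had a promoter peak (odds ratio 3.05, adjusted p = 1.39e-05, Fisher's exact test). Within CpG classes of promoters the odds ratio was 1.86 (adjusted p = 0.0336, exact test). Their strongest were at Rps3a1 (signal 507.3, chromosome 3 from 86142585 to 86142877), Rpl26 (481.0) and Rpl36 (480.4), each within 115 bp of a transcript start. Of 75 genes in cytochrome P450 families 1 to 4, which include the main drug-metabolizing enzymes of the liver, 10 (13.3%) had one (odds ratio 0.270, adjusted p = 0.000107, Fisher's exact test). Within classes of promoter CpG content that difference no longer passed (odds ratio 0.485, adjusted p = 0.143, exact test). The strongest P450 peaks were at Cyp2w1 (432.3), Cyp4f37 (349.6) and Cyp1b1 (275.3). Those at Cyp2w1 and Cyp4f37 lay near internal starts, at Cyp4f37 in the 3' UTR. With 5' ends of genes only, 6 of the 75 had a promoter peak. Of 1093 olfactory receptor genes, 11 (1.01%) had a promoter peak (odds ratio 0.0166, adjusted p = 3.70e-196, Fisher's exact test). Within CpG classes their odds ratio was 0.0318. The strongest were at Olfr557 (233.2), Olfr15 (213.0) and Olfr658 (103.3), with the one at Olfr15 in a coding exon near an internal start.

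Genes of the CTCF and cohesin machinery had a promoter peak in 12 of 19 cases (63.2%, odds ratio 3.02), which did not pass with the optimal list (adjusted p = 0.0898, Fisher's exact test) and passed with the conservative list (odds ratio 4.09, adjusted p = 0.0148, Fisher's exact test) and with either replicate alone. Within CpG classes the odds ratio was 1.87 (adjusted p = 0.763, exact test), and the adjusted p was 0.0691 with the stronger peaks and 0.0873 within 5 kb, and missed the threshold at 5' ends too (Fisher's exact test). Esco1, which acetylates cohesin, had a signal of 436.9 and the cohesin regulator Pds5b 365.7. The cohesin subunit gene Stag1 had 425.5, near an internal start and over the perfect core CCAGCAGAGGGCGG on chromosome 9 from 100643573 to 100643586. Clustered protocadherins, whose promoter choice depends on CTCF in neurons, had a promoter peak in 28 of 57 (49.1%; adjusted p = 0.143, Fisher's exact test), and within CpG classes the odds ratio was 3.07 (adjusted p = 0.000230, exact test). The excess depended on the setting, with odds ratios of 0.519 among the stronger peaks and 0.993 within 5 kb. It passed at 5' ends (2.45, adjusted p = 0.00467) and without replicate 2 (2.09, adjusted p = 0.0213), and not without replicate 1 (1.69, adjusted p = 0.144, all Fisher's exact test). Pcdhga12 (204.6), Pcdhgb6 (152.7) and Pcdhgb7 (143.1) led this list. Hox genes had one in 7 of 39 (17.9%; adjusted p = 0.0888, Fisher's exact test), and within CpG classes fewer than other genes (odds ratio 0.311, adjusted p = 0.0109, exact test). Within 5 kb the direction turned, with 25 of 39 Hox genes near a peak (64.1% against 56.3% of other genes, odds ratio 1.39). Hoxa7 (377.3), Hoxb5 (260.8) and Hoxa5 (212.5) had the strongest. Protocadherin and Hox genes lie in clusters, and these tests treat genes as independent, so their p-values may be too small.

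No list of liver cell type markers passed the test with the optimal peaks and promoters at any annotated start. Hepatocyte genes had a promoter peak in 4 of 27 (14.8%; adjusted p = 0.0898, Fisher's exact test), led by Apob (329.1), Afp (298.0) and Ass1 (109.5). The counts were 4 of 12 for cholangiocytes, the bile duct cells (Jag1 222.7, Krt8 126.2, Onecut1 60.4), 5 of 14 for hepatic stellate cells (Col1a1 327.1, Pdgfra 279.4, Vim 139.5) and 4 of 14 for endothelial cells (Clec4g 446.5, Egfl7 118.5, Erg 40.7), each with an adjusted p of 1.00 in Fisher's exact test. Among blood lineages they were 7 of 21 for erythroid genes (including Zfpm1 407.3 and Tfrc 121.1), 2 of 15 for macrophage and granulocyte genes (Mpo 97.52, Ptprc 25.4) and 1 of 12 for lymphocyte genes (Cd79b 4.90). Their adjusted p-values were 1.00, 0.218 and 0.159 (Fisher's exact test). Of the peaks named here, those at Apob, Afp, Onecut1, Pdgfra, Vim, Clec4g, Egfl7, Zfpm1, Tfrc, Mpo and Ptprc lay near internal starts. Each of them was over 1 kb from the 5' end of its gene. With promoters at 5' ends only, the counts were 2 of 27 hepatocyte, 3 of 12 cholangiocyte, 3 of 14 stellate and 1 of 14 endothelial genes. They were 4 of 21 erythroid, 0 of 15 macrophage and granulocyte and 1 of 12 lymphocyte genes. The lymphocyte list passed with the conservative list (adjusted p = 0.0427, Fisher's exact test) and with either replicate alone. The weak Cd79b peak was not held in these lists. The macrophage and granulocyte list passed when promoters were taken at the 5' end of the gene only (adjusted p = 0.0344, Fisher's exact test). Neither list has a CpG-rich promoter, and within CpG classes the adjusted p was 0.919 for lymphocyte and 0.942 for macrophage and granulocyte genes (exact test).

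No list of metabolic, cell cycle, imprinted or zinc finger genes passed the test against the other protein-coding genes. A promoter peak was found at 11 of 22 cell cycle genes, led by the replication genes Mcm5 (399.7), Mcm2 (359.4) and Rrm2 (315.4). It was found at 10 of 23 cholesterol and bile acid genes (Dhcr7 375.4, Mvd 97.9, Lss 83.1), 5 of 16 glucose metabolism genes (Pfkl 230.5, Pklr 135.0, Gpi1 120.2) and 2 of 7 urea cycle genes (Asl 347.6, Ass1 109.5). It was found at 15 of 36 imprinted genes (H13 434.3, Meg3 233.6, Grb10 138.7) and 144 of 365 zinc finger genes (Zfp398 521.3, Zfp786 484.1, Zfp638 481.7). Their adjusted p-values lay between 0.357 and 1.00 in Fisher's exact test. The peaks named at Mcm2, Dhcr7, Lss, Asl, Meg3, Grb10 and Zfp638 lay near internal starts, over 1 kb from the 5' end of the gene. A few genes, such as Ass1, belong to more than 1 list.

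**Figure D4:**
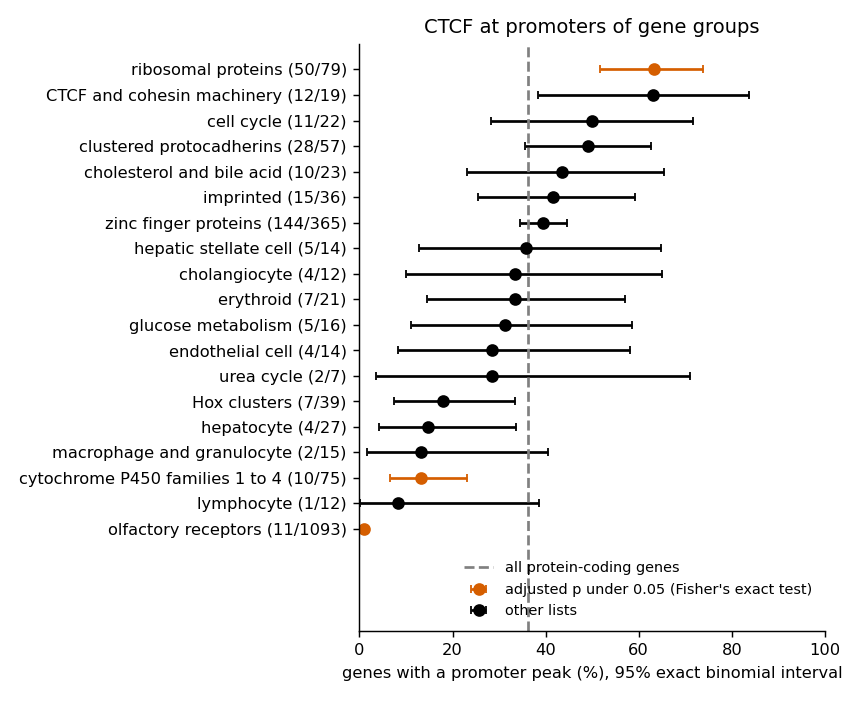
Percent of the genes in each of 19 lists with an optimal IDR peak within 1 kb of a transcript start, with exact 95% binomial intervals and the number with a peak over the number in the list; the dashed line is all protein-coding genes (36.2%). Ribosomal proteins (63.3%), cytochrome P450 (13.3%) and olfactory receptors (1.01%) passed an adjusted p of 0.05.

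At the imprinted pair H19 and Igf2, a noncoding RNA and a fetal growth factor on chromosome 7, 9 peaks lay between 142555529 and 142686816. A group of 4 lay in intergenic sequence 2.16, 2.63, 3.66 and 3.87 kb upstream of the H19 5' end, where the imprinting control region is known to lie, with signals of 117.2, 163.0, 103.3 and 12.2. The last, from 142581868 to 142582151, was matched in replicate 1 only. None of the 4 had the core with 2 or fewer mismatches, and 3 of them had it with 3. Upstream of Igf2 a group of 3 peaks had signals of 21.3, 199.5 and 158.2. The last covered CCAGCAGAGGTCAC, on the reverse strand from 142675856 to 142675869, which has 1 mismatch. Neither gene had a promoter peak.

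**Figure D5:**
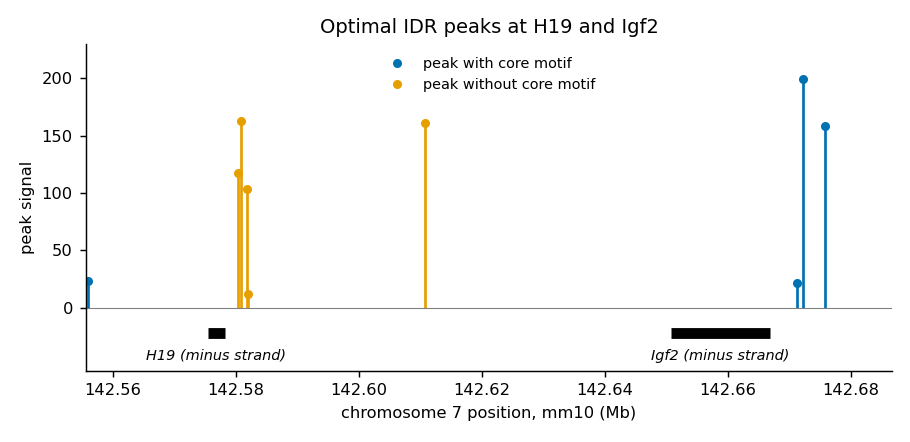
Deposited signal of the 9 optimal IDR peaks from 142555529 to 142686816 on chromosome 7, with peaks with and without the core motif (at most 2 mismatches) in different colors and the H19 and Igf2 genes as bars. The 4 peaks upstream of H19 have signals of 12.2 to 163.0 and no core, and the 3 upstream of Igf2 have signals of 21.3 to 199.5 with a core.

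Other imprinted landmarks differed in where CTCF lay. Meg3 had a promoter peak in a noncoding exon, 776 bp from an internal start, on chromosome 12 from 109542925 to 109543163 (signal 233.6). Peg3 had 1 in its 5' UTR (22.1) and Kcnq1ot1 1 in its noncoding exon (24.5). The nearest peak was 14.9 kb from a start of Dlk1 (340.5), 2.61 kb from one of Igf2r, within Airn (20.5), and 246.9 kb from one of Snrpn (28.4).

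Among 5 landmark genes of secreted liver proteins, Afp had a promoter peak and Alb, Ttr, Serpina1a and Apoa1 had none. The nearest peak was 27.3 kb from a start of the albumin gene Alb (32.8), 5.59 kb from one of Ttr (12.9) and 114.5 kb from one of Serpina1a (213.7). In Apoa1 a coding exon carried a peak of 184.8, 1.32 kb from a start. Afp, the fetal counterpart of albumin, carried an intronic peak of 298.0 at chromosome 5 from 90500800 to 90501054, 601 bp from an internal transcript start. The liver regulator Hnf4a had its nearest peak in an intron 6.02 kb from a start (24.3). Among erythroid landmarks, the adult beta-globin genes Hbb-bt and Hbb-bs shared their nearest peak, on chromosome 7 from 103806978 to 103807195 (240.7), 6.92 and 20.6 kb from their starts. Hba-a1 had 1 at 2.28 kb (39.8) and Gata1 a promoter peak of 60.7, 109 bp from an internal start. Myc had a peak of 143.0 in its 5' UTR, 21 bp from a start, without the core. Promoter peaks were also found at Ctcf itself (83.5) and at the cohesin subunit gene Rad21 (50.5). Shh had its nearest peak at 2.72 kb (183.6), and Hoxa9 at 4.38 kb, in the 5' UTR of Hoxa7 (377.3).

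Chromosome X carried fewer peaks than the autosomes. The density was 8.41 peaks per Mb on X and 22.6 on autosomes, a ratio of 0.371 (replicates alone 0.367 in both). Among autosomes chromosome 11 was highest, with 35.9 peaks per Mb, and chromosome 3 lowest, with 16.8. No optimal peak lay on chromosome Y. On X, Xist, the noncoding RNA of X inactivation, had a promoter peak from 103484124 to 103484363 (signal 276.7) over the perfect core CCAGCAGGTGGCAG, within a noncoding exon of its antisense gene Tsix. The nearest peak to a Tsix start was 3.77 kb away (173.4). Firre, a noncoding RNA gene known for its repeated CTCF sites, had 31 peaks within the gene and 20 kb around it. Its promoter peak, 896 bp from an internal start and not at the 5' end of the gene, had a signal of 129.0.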

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

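Of the tests in this part, those on mismatches, on signal per site on chromosome X and on weak optimal peaks were chosen after the results were seen, and the test on repeated sequence was added once the occupancy of perfect cores on X was known, before its own value. The promoter share by mismatches was tested after the comparison with shuffled bases had given its value, signal per site on X was left open only once classes of cores with mismatches had been compared, and holding intervals of the summit distance and of calls in both replicates against the bounds was decided after their values were seen. Signals outside the peaks analysed in the report were looked at as well. The optimal list held 23 peaks on 9 scaffolds, 11 of them on JH584304, with signals up to 470.1. The conservative list held 4636 peaks that the optimal list lacked; their median signal was 17.2, and 46.2% of them carried the core, compared with 46.0% of the 6992 peaks in the optimal list only. Among the 20000 strongest pooled peaks, 5 were outside the optimal list. The 3 strongest of these lay in intergenic sequence, with Cr2 (64.9 kb away on chromosome 1, signal 303.3), Gm21060 (30.4 kb, chromosome 19, 275.9) and Gm6020 (15.7 kb, chromosome 19, 274.8) as the nearest genes. Each was also high in both replicates, such as ranks 5700 and 5251 for the peak near Cr2.

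Peaks without the core were more often at promoters (34.1% against 15.1%). Tables argue against cores with 3 mismatches as the only cause of this difference. The promoter share was 30.6% with exactly 3. It was 40.9% (39.6 to 42.2) with 4 or more, 2.23 times the 18.4% with at most 3. These shares were not matched for signal, which was lower where the core had more mismatches. Missed cores do remain a candidate explanation for many of these peaks, since 59.4% of the 5605 at promoters had a core with 3 mismatches, 2.21 times the 26.9% after shuffling (69.6% of the other peaks without the core), and weaker cores were not tested. A lack of a fixed position, as in open promoters caught at random, stays open: at like signal, summits of the replicates lay 1.9 bp farther apart at promoter peaks without the core (bootstrap interval 1.1 to 2.6), across the bound of 2 bp set against it and under the 5 bp set for it, but the difference ran from -2 to 6 bp and was 4, 4.5 and 6 bp in the weakest groups. The design has 1 group, so no biological explanation was tested.

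Chromosome X had few peaks (density ratio 0.371). Perfect cores were rarer there, at 0.554 of the autosomal density, which leaves part of the deficit over, since 52.7% of perfect cores on X lay near a peak against 85.5% on autosomes. Repeated sequence may add to this: among cores in 100 bp of sequence seen once, the shares were 67.7% and 87.3%, a ratio of 0.776 (0.693 to 0.852), whose upper bound just exceeds the 0.85 set beforehand. Signal per site was lower at perfect cores, with a median of 0.586 of the autosomal one (bootstrap interval 0.452 to 0.677). It was 0.591 and 0.611 in the replicates alone, but this covers 124 X peaks. The ratio was 0.894 (0.843 to 0.971) over all 1438, and 1.28 (1.14 to 1.48) at cores with 3 mismatches, so lower signal per site stays open. Of the 264 X peaks with 3 mismatches, 20 lay within Firre. The median signal was 134.4 over all 28 Firre peaks and 53.4 over the 264. The interval treats these peaks as independent sites. The sex of the pooled mice was not collected, so copy number and binding were not separated.

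The optimal list held 348 peaks ranked beyond 100000 in the pooled list. Shoulders of stronger peaks are a candidate explanation: 87.4% lay within 1 kb of a pooled peak among the 100000 strongest, against 20.1% of other peaks of like rank. A summit within 100 bp in both replicate lists was found for 8.91% against 7.85%, a ratio of 1.13 (0.781 to 1.58). A shoulder whose replicate summit lay at the stronger peak would fail this rule. The test therefore cannot decide whether being called in both replicates sets these peaks apart. The 348 peaks lay at promoters in 49.3% of cases, against 18.7%, and no biological explanation was tested.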

How the results depend on the processing

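The alternative with pairs 50 to 200 kb apart was added after the results were seen. No paired analysis was possible because the series has 1 group. Of 235 alternative values, 147 kept their direction and side of the threshold or moved by less than the replicate spread, and 35 turned direction. A further 39 were counted as moved, 12 passed a threshold that the main value missed, and 2 missed one that it passed. The shares listed for displaced summits are the main shares again, so they could only count among the 147. The replicates' shared peaks were 88.3% with overlap by 1 bp, 83.7% with 50% reciprocal overlap, 85.3% within 50 bp and 92.0% among the 10000 strongest, and rho was 0.958 with overlap and 0.975 in the conservative list. The promoter share was 20.2% in the conservative list, 18.5% among the stronger 28610 peaks, 14.8% within 500 bp, 45.7% within 5 kb and 20.5% to 20.7% with 1 replicate left out. The motif share was 72.3% in the conservative list, 84.0% among the stronger peaks, 38.4% with at most 1 mismatch, 90.3% with at most 3, 73.4% within 100 bp and 70.7% to 71.1% with 1 replicate left out. The X to autosome ratio was 0.374 in the conservative list, 0.343 among the stronger peaks, 0.378 without gaps and 0.367 with either replicate left out. The exon share over background turned to 0.843 with displaced summits, and the intron share to 0.860 there, 0.968 among the stronger peaks and 0.861 within 5 kb. The convergent deficit held in the 6 alternatives that keep close pairs (20.2% to 22.9%) and turned to an excess of 28.2% for pairs 50 to 200 kb apart. The divergent share was above the shuffled range at 26.9% among the stronger peaks, 26.0% within 50 kb and 27.1% with at most 1 mismatch. It was within the range at 25.15% in the conservative list and at 24.86% to 25.03% with 1 replicate left out. For pairs 50 to 200 kb apart it was 20.2%, below the shuffled range of 23.5% to 26.5%. Lists past the threshold numbered 3, and 5 in the conservative list, 5 with 5' ends only, 4 with CpG classes and 5 to 6 with 1 replicate left out; ribosomal proteins and olfactory receptors passed throughout. Odds ratios turned, each short of the threshold, in the conservative list (stellate 1.05, glucose 1.13), among the stronger peaks (stellate 1.21, erythroid 1.04, cholesterol 0.662, glucose 1.02, urea 1.77, protocadherins 0.519, zinc finger 0.920), within 5 kb (cholangiocyte 2.33, stellate 1.03, endothelial 1.03, erythroid 1.26, glucose 2.33, urea 1.03, Hox 1.39, protocadherins 0.993, zinc finger 0.898), at 5' ends (glucose 1.15) and within CpG classes (cholangiocyte 1.03, stellate 1.22, endothelial 1.09, erythroid 1.29). With 1 replicate left out they ran from 0.999 to 2.10 for cell cycle and from 0.701 to 1.31 for urea cycle genes. The cause of these turns was not tested. The depth of the libraries is unknown, which limits what can be said of weak peaks.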

Other observations

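The values in this part were chosen after the results were seen and no explanation is offered for them. Within the Firre gene, from 50555744 to 50635321 on chromosome X, 28 optimal peaks lay with signals from 41.2 to 218.7. Only 3 of them had the core with at most 2 mismatches, while 20 had it with exactly 3. The densest 100 kb windows held 22 peaks each, against a median of 3 over 15798 windows with a peak. They lay on chromosome 10 from 79700001 to 79800000, over Bsg, Hcn2, Polrmt, Fgf22 and neighbours, and on chromosome 11 from 98700001 to 98800000, over Csf3, Med24, Thra, Nr1d1 and Msl1. The window on chromosome 7 from 141400001 to 141500000, with 21 peaks, covers Taldo1, Pnpla2 and Cd151, among others.

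Perfect matches to the core were bound at most sites. Of 6323 on autosomes, 5407 (85.5%, 95% interval 84.6 to 86.4) lay within 50 bp of an optimal summit, from 77.7% on chromosome 5 to 90.6% on chromosome 11. Chromosome Y had 383 perfect matches and no peak near any, and 33 of them lay in 100 bp of sequence seen once among all matches. Repeat-masked bases held 22.4% of all summits, compared with 34.3% of the bases of the autosomes and X. The share was 25.6% at peaks with the core and 14.5% at those without it.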
